A study of Drosophila melanogaster with 10 samples.

How the data were processed

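RNA was taken from whole bodies of wild-type Drosophila melanogaster after injection of house dust mite extract or of phosphate-buffered saline, and messenger RNA libraries were sequenced, per the labels. The labels give 5 libraries per treatment, numbered 1 to 5 in each group. The treatment label set the group of each library, the numbers were used as names only, and libraries with different numbers were treated as separate replicates. No label says what the replicates are.

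The deposited table holds 12742 genes and, for each library, an estimated count, a TPM, an FPKM and a scaled count. HISAT2 and RSEM 1.3.1 are named, per the submitters' processing notes, and the role of each, the genome build and the annotation are not given in the sources used here. The expected counts were deposited without normalization, as seen from their totals of 18256123 to 19343932 and from 1280 to 1335 genes per library with a value that is not whole. The authors deposited TPM values that sum to 1000000 per library, up to rounding, and FPKM values scaled by gene length and library size, per the file headers. The scaled counts, a normalized signal made by the authors, equalled the count rounded up times 1 factor per library (0.952 to 1.082) to within 1% for 100% of genes with a count, and were not used in tests. A further 8 columns of group averages were not used. Gene names are those of the table, and 12740 of its gene identifiers matched the reference gene table of assembly Release 6 plus ISO1 MT. That reference served for names and for the gene lengths of a later check on length, and no coordinates are given. No gene lacked a name, and 0 genes had a count of 0 in every library.

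Expected counts were rounded to whole numbers. The main test was edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM factors, a robust quasi-likelihood fit (glmQLFit, glmQLFTest) with group as the only term, and Benjamini-Hochberg adjustment over all 9950 genes that passed the filter. Genes with an adjusted p under 0.05 were called. CPM values use the TMM-adjusted library sizes. The SE of a log2 fold change was computed from the fold change and its F statistic. The biological coefficient of variation was 24.7%. The 20 most abundant genes took 9.42% to 11.27% of the counts of a library.

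A total of 39 gene lists on fly immunity, stress, metabolism and tissues were written, with their members and the rule for naming genes, before the data were examined, as were the test, the threshold and the alternatives except those listed below as added. Of these lists, 35 had at least 5 measured genes and were tested with camera of limma 3.58.1 on log2 CPM at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes. The directional p of fry tests whether the genes of a list move, on balance, one way, its mixed p whether they change in either direction, and neither compares the list with other genes. A list score is the mean log2 CPM of its measured members in a library, and groups of scores were compared by exact permutation of the 10 libraries, whose smallest possible two-sided p is 0.00794. The Turandot, lysozyme, accessory gland and testis lists had fewer than 5 genes past the count filter and were tested with camera only under the looser filter.

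The text names (a) the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with groups that do not overlap and a mean count of at least 50 in the higher group, or, as no gene passed, the 10 with the lowest p. It names (b) up to 4 members per list past the threshold with the lowest p, or, if none passed, the 1 with the lowest p, and (c) any measured antimicrobial peptide, Bomanin or Turandot gene. It also names (d) genes that a closer look at a library, a composition check or, beyond the rule as first written, another tool's or setting's call is about, chosen after their values were seen, which are ninaE, Arr1, trpl, LysD, LysX, Nazo, CG42825, PGRP-SC1a, Yp1, Acp26Aa, betaTub85D, bam, gdl, Vago, His3:CG33845, Unc-115b, CG9897 and CG8740.

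Within groups, no pair of libraries agreed within sampling noise. A chi-square statistic per gene, near 1 for repeated counting of the same library, lay between 20.2 and 137. The test was tried on simulated data drawn from the measured means, library sizes and gene-wise spread, with 200 genes changed by known folds. In a further simulation in which the genes of 1 list were shifted, camera called 1 list, the shifted one, with either correlation. The simulated genes vary independently, which the measured ones do not.

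The alternatives were RLE factors, no composition factor, upper quartile factors, a looser and a stricter count filter (at least 50 counts in at least 5 libraries), DESeq2 1.42.0, limma-voom without and with sample quality weights, an exact Wilcoxon test, limma on log2(TPM + 1) and log2(TPM + 0.1), a block by replicate number, a 2-fold minimum, an adjusted p of 0.01, omission of the 20 most abundant genes and omission of each library in turn. For lists they were an estimated correlation, fry, ranks, RLE factors, the block, the looser filter and omission of each library. Added after seeing the data were component 1 as a covariate, 1 or 2 surrogate variables from sva 3.50.0, omission of PBS replicate 1 and HDM replicates 2 and 5 together, an estimated correlation together with omission of each library, component 1 or the looser filter, and exact permutation of list scores. Counts under 100 splits of the libraries, out of 126 possible, were drawn with a fixed seed.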

Results

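Gene expression was measured by RNA sequencing in whole wild-type fruit flies (Drosophila melanogaster) that had been injected either with an extract of house dust mite (HDM), a common source of inhaled allergens, or with its vehicle, phosphate-buffered saline (PBS). Each group held 5 libraries, and the 10 libraries had total estimated counts of 18256123 to 19343932 per library. Nothing in the labels says that replicates came from separate animals or pools, so every p-value measures only the spread between these samples. The single comparison, HDM against PBS, asks how the extract altered the transcriptome of the whole fly.

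No gene differed between HDM-injected and PBS-injected flies beyond the spread between libraries. Of 9950 genes tested with edgeR's quasi-likelihood test, 0 passed an adjusted p of 0.05, and the lowest adjusted p was 0.94. The antimicrobial peptide genes, the Bomanins (small secreted peptides induced through the Toll pathway) and the Turandot genes (secreted stress proteins) had 0 members past the threshold. Of the 10 genes with the lowest p, 7 had smaller values after HDM, among them chp, a member of the photoreceptor list, and Cpn and Pdh. At an unadjusted p under 0.05 there were 214 genes, 2.15% of those tested, of which 77 had larger and 137 smaller values after HDM. If no gene differed, a share of about 0.05 would be expected on average, so the 214 are no excess. The number at this level was 655 without PBS replicate 4 and 112 without PBS replicate 1. It was 132 without PBS replicate 3, 119 without HDM replicate 1 and 137 without HDM replicate 4. Each of these omissions called 0 genes. The lowest adjusted p by edgeR was 0.0943 without PBS replicate 4 and 0.304 without HDM replicate 2. It was at least 0.78 with any other library left out. DESeq2's Wald test called 1 gene with 300 at an unadjusted p under 0.05. limma-voom called 0 with 172 such genes, or 371 with sample quality weights. An exact Wilcoxon rank-sum test on counts scaled to a common library size (CPM) called 0 with 132. Its smallest possible p is 0.00794, so a call over 9950 genes needed far more fully separated genes than the 30 seen. The 0 from that test therefore adds no separate evidence. limma on log2(TPM + 1) and on log2(TPM + 0.1) called 0 genes as well, with 221 and 236 at an unadjusted p under 0.05. The DESeq2 call was the histone gene copy His3:CG33845 (adjusted p = 0.0125), which had a CPM of 0 in all 5 PBS libraries and in HDM replicate 3, and 2.06, 0.418, 4.39 and 3.49 in HDM replicates 1, 2, 4 and 5. It is one of a family of near-identical copies among which reads can be divided arbitrarily, its value is therefore uncertain, and it was chosen for naming after its values were seen.

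The 10 genes with the lowest p included 1 member of the photoreceptor list, chp. Cpn and Pdh, which are in none of the lists, were set beside chp after the values were seen, and no test covers the 3 together. PBS replicate 1 was the highest of the 10 libraries in all 3. Pdh, photoreceptor dehydrogenase (gene identifier 39812 in the deposited table), had 43.9 ± 18.9 CPM in PBS and 23.2 ± 1.83 CPM in HDM libraries (SD, n = 5), a log2 fold change of -0.92 ± 0.24 (SE). Cpn, which encodes the photoreceptor protein calphotin (identifier 41474), had a log2 fold change of -1.08 ± 0.28, and chp, which encodes the photoreceptor surface protein chaoptin (identifier 43690), had -1.11 ± 0.33. PBS replicate 1 had 75.9 CPM of Pdh, 5.82 CPM of Cpn and 15.8 CPM of chp, where the next highest PBS library had 45.4, 3.26 and 7.81 CPM. Without it the log2 fold changes were -0.63 for Pdh, -0.8 for Cpn and -0.69 for chp. The gene with the lowest p, phu (identifier 41135), had 0.867 ± 0.407 CPM in PBS and 3.36 ± 1.9 CPM in HDM libraries, a log2 fold change of 1.95 ± 0.47. The other 6 were CG44837 at -1.3 ± 0.36, the cuticle protein gene Cpr72Ec at -0.84 ± 0.24, CG45002 at -1 ± 0.28, CG9394 at -0.91 ± 0.27, CG6428 at 0.17 ± 0.05 and REPTOR, a transcription factor acting downstream of the TOR kinase, at 0.13 ± 0.04. In each of these 10 genes all 5 HDM libraries lay on the same side of the PBS mean, and each had an adjusted p of 0.94 by edgeR. Across all tested genes, 30 had HDM values that did not overlap the PBS values, where random labelling gives 0.794% of genes, or 79.

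Among the immune effector genes the libraries of one group differed more than the groups did. Drosomycin (Drs), an antifungal peptide, had 203 ± 102 CPM in PBS and 447 ± 460 CPM in HDM libraries (SD, n = 5), a log2 fold change of 1.14 ± 0.74 (SE, adjusted p = 0.94 by edgeR). Its values were 1170 CPM in HDM replicate 2 and 623 CPM in HDM replicate 5, but 78.6, 102 and 260 CPM in HDM replicates 1, 3 and 4, against 87.3 to 313 CPM in PBS libraries. Drosocin (Dro), the antimicrobial peptide gene with the lowest p, likewise had 25 and 19.2 CPM in HDM replicates 2 and 5 and 1.54 to 4.04 CPM in the other HDM libraries, and its log2 fold change was 1.69 ± 0.71. The diptericins DptA and DptB had log2 fold changes of 2.11 ± 0.97 and 1.7 ± 0.89, and metchnikowin (Mtk) had 0.12 ± 1.11. HDM replicate 5 had 32.7 CPM of DptA, the other HDM libraries 0.463 to 7.9 CPM. Without it the log2 fold changes were 0.77 for DptA and 1.06 for DptB. Without HDM replicate 2 they were 0.39 for Drs, 1.09 for Dro and 1.93 for SPH93. Of the 13 measured antimicrobial peptide genes, 10 had larger and 3 smaller mean values after HDM, and 0 passed over all genes tested or adjusted over the list alone. Of the 20 measured Bomanins and other Toll effectors, 11 had larger and 9 smaller values, and again 0 passed by either adjustment. BomS1 had 189 ± 162 CPM in PBS and 170 ± 123 CPM in HDM libraries, with 377 and 333 CPM in PBS replicates 1 and 2 and 34.1 and 32.2 CPM in PBS replicates 4 and 5. The sign of its log2 fold change, -0.15 ± 0.77, turned positive with limma-voom (0.21) and without PBS replicate 1 (0.26), PBS replicate 2 (0.11) or HDM replicate 3 (0.09). That of Mtk turned negative without PBS replicate 4 (-0.18), PBS replicate 5 (-0.19), HDM replicate 2 (-0.64) or HDM replicate 5 (-0.06). SPH93, a serine protease homolog in this list, had 171 CPM in HDM replicate 2 and 0.625 CPM in PBS replicate 5, and a log2 fold change of 3.02 ± 1.2. All 4 measured Turandot genes had larger mean values after HDM, namely TotA at a log2 fold change of 0.91 ± 0.87, TotC at 0.97 ± 0.94, TotM at 1.25 ± 0.55 and TotX at 0.34 ± 0.63. TotA ranged from 3.75 to 48.5 CPM in PBS and from 9.78 to 75.4 CPM in HDM libraries. Without HDM replicate 3 the log2 fold changes of TotA and TotC were 0.36 and 0.12 and that of TotX turned negative (-0.38). Without PBS replicate 1 the 3 values were 1.75, 1.97 and 0.78. Over all genes and adjusted over the list alone, 0 Turandot genes passed. The difference in the mean log2 CPM of the Turandot genes was 1.07, with all 5 HDM libraries above the PBS mean (exact permutation p = 0.206, two-sided), or 0.68 without HDM replicate 3. With the looser count filter 5 Turandot genes could be tested as a list. Camera called them up at the preset correlation (adjusted p = 0.00354, and adjusted p = 0.848 with an estimated correlation).

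**Figure D1:**
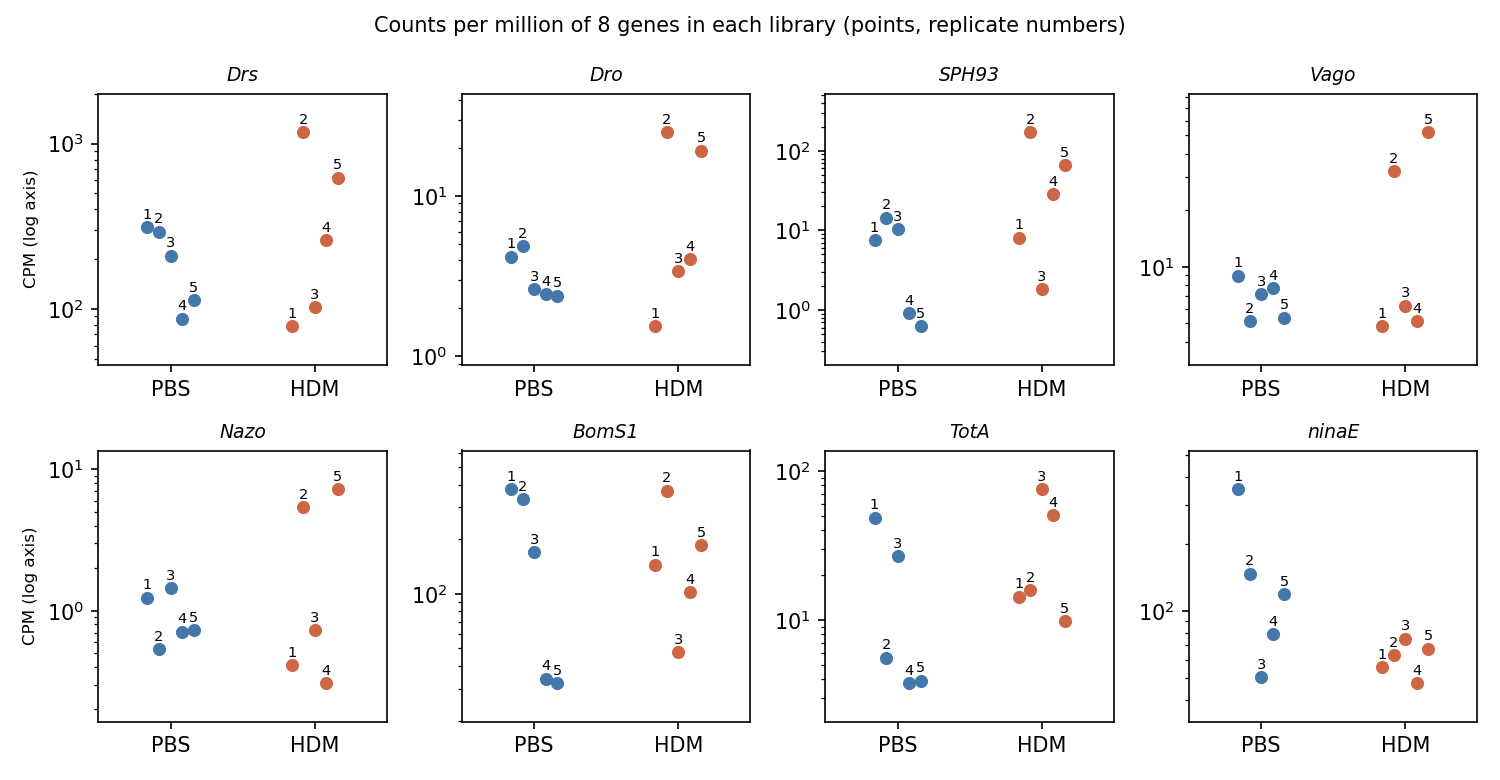
CPM on a log axis for 7 defence and stress genes and the rhodopsin gene ninaE in each of the 10 libraries, with points numbered by replicate. Drs, Dro, Vago and Nazo are highest in HDM replicates 2 and 5, while ninaE is highest in PBS replicate 1 at 352 CPM.

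As a group, genes of oxidative phosphorylation, photoreceptors, glycolysis, muscle, neurons and digestive enzymes had smaller values after HDM, and ribosomal protein genes and genes of RNA interference and STING signalling had larger ones, at a preset inter-gene correlation of 0.01. With this setting limma's camera placed 8 of 35 lists under an adjusted p of 0.05. With the correlation estimated from the data 0 of the 8 calls held, and the lowest adjusted p was 0.919. That setting rarely calls a list in these libraries. In a split of the libraries that ignored the injection, edgeR called 3424 genes and camera 21 lists at the preset correlation. With an estimated correlation camera called 0 lists there. A call lost under an estimated correlation therefore says little on whether the list moved. The preset correlation does not settle this either, as 76 of 100 splits gave at least 8 lists. fry's directional test called 0 lists (lowest adjusted p = 0.948) and its mixed test called 0 lists (lowest adjusted p = 0.79). In every list, 0 members passed over all genes tested and 0 passed adjusted over the list alone. The mean log2 CPM of the list lay below the PBS mean in 5 of 5 HDM libraries for oxidative phosphorylation, photoreceptors, muscle and neurons, in 4 for glycolysis and in 3 for digestive enzymes, and above it in 3 for ribosomal proteins and 2 for RNA interference and STING.

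Of 58 nuclear-encoded oxidative phosphorylation genes, 57 had smaller and 1 larger mean values after HDM (camera adjusted p = 3.4e-20, and adjusted p = 0.919 with an estimated correlation), with a median log2 fold change of -0.24. UQCR-6.4, a subunit of respiratory complex III, had 133 ± 27.6 CPM in PBS and 100 ± 2.89 CPM in HDM libraries (SD, n = 5), a log2 fold change of -0.41 ± 0.13. Of 16 photoreceptor genes, 15 had smaller values (camera adjusted p = 1.77e-08, and adjusted p = 0.919 with an estimated correlation). The rhodopsin gene ninaE had a log2 fold change of -1.27 ± 0.46, the arrestin gene Arr1 -1.81 ± 0.67 and the phototransduction channel gene trpl -0.8 ± 0.3, all chosen for naming after their values were seen. PBS replicate 1 stood above the other 9 libraries in these genes, with 352 CPM of ninaE against 47.4 to 147 CPM elsewhere and 83.9 CPM of Arr1 against 5.78 to 25.3 CPM. All 25 glycolysis and sugar store genes, led by the trehalase gene Treh at -0.29 ± 0.15, had smaller values (camera adjusted p = 7.91e-05, and adjusted p = 0.919 with an estimated correlation). All 19 muscle genes, led by Zasp52 at -0.43 ± 0.23, had smaller values (camera adjusted p = 0.00012, and adjusted p = 0.925 with an estimated correlation). All 13 neuron genes, led by the monoamine transporter gene Vmat at -0.45 ± 0.23, had smaller values (camera adjusted p = 0.000442, and adjusted p = 0.919 with an estimated correlation), and this call was also lost without PBS replicate 1 (adjusted p = 0.169). PBS replicate 1 had the highest score of the 10 libraries in each of these lists, at 0.48 above their mean for oxidative phosphorylation, 0.41 for glycolysis, 0.67 for muscle and 0.98 for neurons. Without it the log2 fold changes were -0.68 for ninaE, -0.82 for Arr1, -0.42 for trpl, -0.22 for Zasp52 and -0.18 for Vmat. Without PBS replicate 3 that of Treh was -0.19. The differences in mean log2 CPM between the groups were -0.22 for oxidative phosphorylation, -0.56 for photoreceptors, -0.15 for glycolysis, -0.25 for muscle and -0.29 for neurons. Without PBS replicate 1 they were -0.13, -0.27, -0.07, -0.12 and -0.08. Without PBS replicate 4 they were larger in size for oxidative phosphorylation (-0.34), glycolysis (-0.26) and muscle (-0.44). Glycolysis had -0.1 and muscle -0.13 without PBS replicate 3, and -0.08 and -0.16 without HDM replicate 1. With PBS replicate 1 and HDM replicates 2 and 5 left out together, an alternative added after the data were seen, glycolysis (adjusted p = 0.0653) and muscle (adjusted p = 0.256) were no longer called.

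Of 36 digestive enzyme genes, 25 had smaller values (camera adjusted p = 0.000967, and adjusted p = 0.925 with an estimated correlation). Jon25Bii, a gut serine protease gene, had a log2 fold change of -1.55 ± 0.57. The call was lost without PBS replicate 1 (adjusted p = 0.0532), without PBS replicate 3 (adjusted p = 0.206), without HDM replicate 1 (adjusted p = 0.501) and with component 1 of the expression values as a covariate (adjusted p = 0.264), which was added after the data were seen. The 4 lysozyme genes that passed the count filter, too few for the list test, all had smaller values, with LysB at -2.17 ± 0.74 and LysD at -1.5 ± 0.57. Without PBS replicate 1, which had 142 CPM of LysB, that of LysB was -1.35. The difference in their mean log2 CPM was -1.53, with all 5 HDM libraries below the PBS mean (exact permutation p = 0.0476, two-sided, not adjusted, 1 of 39 lists examined), and 0 lysozyme genes passed adjusted over the list alone, where the lowest adjusted p was 0.0522. With the looser filter 6 lysozyme genes could be tested as a list. Camera called them down at the preset correlation (adjusted p = 0.00501, and adjusted p = 0.848 with an estimated correlation). One of those 6, LysX, went the other way, with 0.279 ± 0.208 CPM in PBS and 5.67 ± 8.39 CPM in HDM libraries. HDM replicates 2 and 5 had 19 and 8.93 CPM of it. These lysozyme genes are close paralogs, so reads may be divided among them uncertainly.

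Of 87 ribosomal protein genes, 75 had larger values, with a median log2 fold change of 0.04 and RpS20 at 0.13 ± 0.06 (camera adjusted p = 0.000994, and adjusted p = 0.925 with an estimated correlation). The call was lost without PBS replicate 5 (adjusted p = 0.313) and without HDM replicate 1, 2 or 5 (adjusted p = 0.0834, 0.491 and 0.257). Of 12 RNA interference and STING genes, 10 had larger values (camera adjusted p = 0.0383, and adjusted p = 0.919 with an estimated correlation). Vago, a secreted antiviral factor gene, had 6.87 ± 1.62 CPM in PBS and 20.1 ± 21.3 CPM in HDM libraries, with 32.2 and 52 CPM in HDM replicates 2 and 5 and 4.84, 6.22 and 5.16 CPM in HDM replicates 1, 3 and 4. Its log2 fold change was 1.55 ± 0.7, or 0.82 without HDM replicate 5. That list's call was lost without PBS replicate 2, 4 or 5 (adjusted p = 0.0607, 0.165 and 0.0691) and without HDM replicate 2 or 5 (adjusted p = 0.282 and 0.407).

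**Figure D2:**
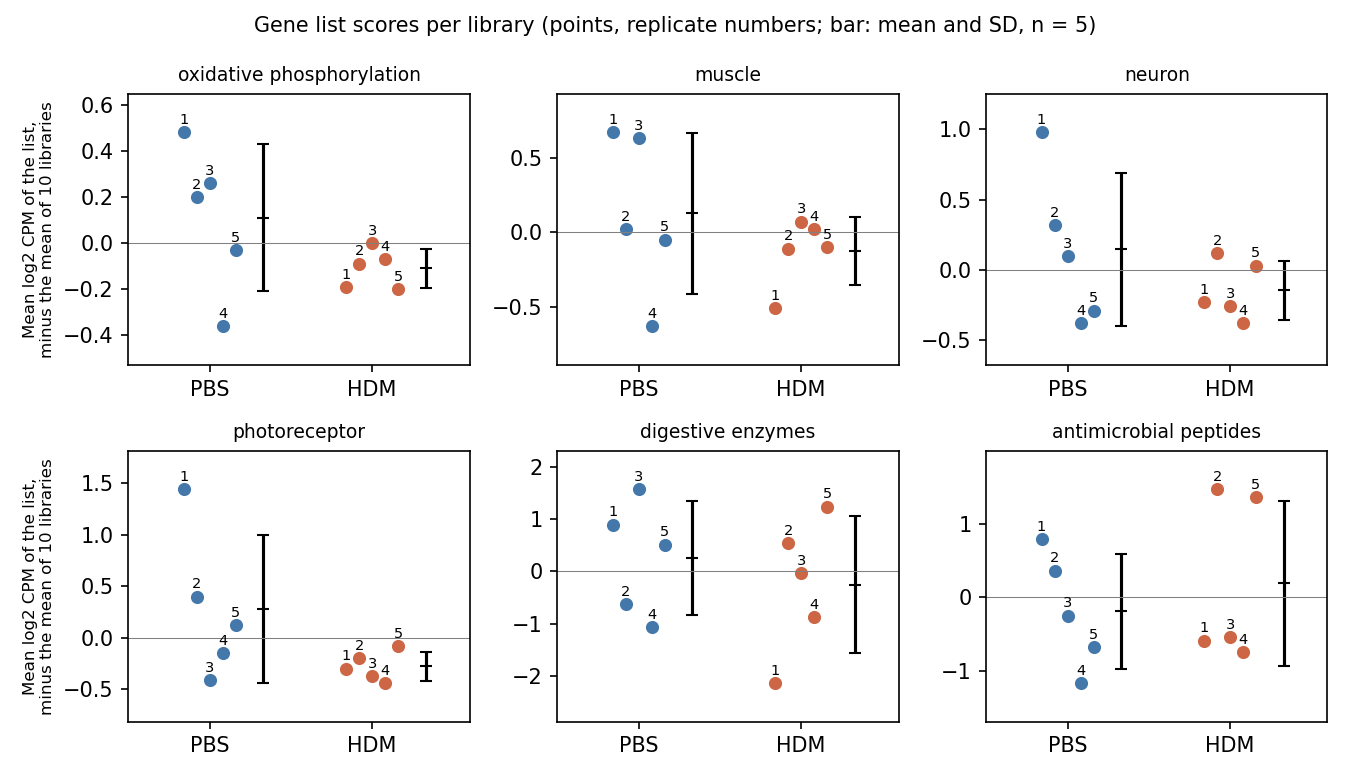
Mean log2 CPM of 6 gene lists in each library, given relative to the mean of the 10 libraries, with replicate numbers beside the points and a bar for the group mean and SD (n = 5). PBS replicate 1 has the highest photoreceptor score, 1.44, and HDM replicates 2 and 5 have the highest antimicrobial peptide scores, 1.47 and 1.36.

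The remaining immune and stress lists did not pass camera's threshold at the preset correlation with all 10 libraries. The antimicrobial peptides had an adjusted p of 0.383 and the Bomanin list 0.707. Without PBS replicate 1, however, camera called the antimicrobial peptides (adjusted p = 0.0151), Bomanins (0.00335), pattern recognition (0.000393), the Toll pathway (0.0244), serpins (0.00346) and JNK genes (0.0151). With an estimated correlation these calls were lost, with an adjusted p = 0.837 for the Toll pathway and an adjusted p = 0.857 for the other 5. Without HDM replicate 1 it called the antimicrobial peptides (0.0377) and pattern recognition (0.0247), without PBS replicate 2 hemocyte markers (0.0359) and heat shock (0.0245), and without HDM replicate 5 hemocyte markers (0.00212). With an estimated correlation these were lost too, at an adjusted p = 0.946 without HDM replicate 1, adjusted p = 0.895 without PBS replicate 2 and adjusted p = 0.805 without HDM replicate 5. With component 1 of the expression values as a covariate, added after the data were seen, it called the antimicrobial peptides (0.0135), Bomanins (0.0044), pattern recognition (5.4e-06), the Toll pathway (0.045) and serpins (0.000342). With that covariate and an estimated correlation 0 lists were called, at an adjusted p = 0.708 for the antimicrobial peptides and Bomanins and adjusted p = 0.448 for the other 3. Pattern recognition genes had an adjusted p of 0.383 over 19 members, led by PGRP-LE at a log2 fold change of 0.13 ± 0.04. The Toll pathway had 0.288 over 17 members, led by the receptor gene Tl at 0.16 ± 0.07, and the Imd pathway had 0.0948 over 18 members, led by Fadd at 0.2 ± 0.1. JAK-STAT genes had 0.383, with the cytokine gene upd3 at 0.72 ± 0.47. Melanization genes had 0.731 (yellow-f, 1.23 ± 0.55), serpins 0.662 (Spn88Eb, 1.43 ± 0.63), clotting genes 0.353 (Lsp2, -1.95 ± 1.13), hemocyte markers 0.0948 (Pxn, -0.38 ± 0.3) and lamellocyte markers 0.731 (cher, -0.19 ± 0.12). Lsp2 had 49.9 CPM in PBS replicate 1 and 0.608 to 14.2 CPM in the other PBS libraries. Its log2 fold change was -0.59 without that library. The sign of Lsp2 turned positive under limma-voom with sample quality weights (0.51). Without PBS replicate 1 the log2 fold changes of Pxn and cher were -0.24 and -0.07, without HDM replicate 1 those of Pxn and upd3 were -0.2 and 0.46, and without HDM replicate 2 that of yellow-f was 0.61. Heat shock genes had 0.383 (Hsp67Bc, -0.57 ± 0.25), JNK and wounding genes 0.763 (puc, 0.2 ± 0.1), cell death genes 0.707 (Debcl, 0.07 ± 0.05, or 0.04 without PBS replicate 1 or HDM replicate 3), redox defence genes 0.707 (Sod2, -0.15 ± 0.1, or -0.09 without PBS replicate 1), the unfolded protein response 0.129 (Ire1, 0.07 ± 0.06, or 0.04 without PBS replicate 2 or HDM replicate 1 and 0.11 without PBS replicate 4) and autophagy 0.707 (Atg16, 0.13 ± 0.06).

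The other detoxification, metabolic and tissue lists did not pass either. Camera's rank-based form did call cytochrome P450 genes (adjusted p = 0.0474) and fat body genes (adjusted p = 0.0485). With an estimated correlation each had an adjusted p = 0.925. Glutathione S-transferases had an adjusted p of 0.662 (GstE1, 0.09 ± 0.05), cytochrome P450 genes 0.0948 (Cyp6a20, -0.52 ± 0.22), iron and metal handling 0.74 (MtnE, 0.75 ± 0.48, or 0.44 without HDM replicate 1), lipid storage and transport 0.707 (Mtp, 0.13 ± 0.04), insulin and FOXO genes 0.933 (InR, 0.09 ± 0.06), and chitin and chitinase-like genes 0.594 (Cht10, 0.4 ± 0.2). Clock genes had 0.0948 (to, -0.58 ± 0.22), Malpighian tubule and nephrocyte genes 0.0948 (Best2, -0.31 ± 0.22, or -0.2 without PBS replicate 1 and -0.19 without HDM replicate 1) and fat body genes, again led by Lsp2, 0.0948. Cytochrome P450 genes were called without PBS replicate 2, 4 or 5 (0.0234, 0.0249 and 0.023) and without HDM replicate 2 or 5 (0.00374 and 0.00705). Fat body genes were called without PBS replicate 2 or 4 (0.0359 and 0.0146) or HDM replicate 5 (0.0359). Clock genes were called without PBS replicate 2 (0.0359) or HDM replicate 5 (0.0461), and Malpighian tubule and nephrocyte genes without HDM replicate 2 or 5 (0.0475 and 0.0121). So were chitin genes without HDM replicate 5 (0.0359). With an estimated correlation all of these calls were lost, at an adjusted p = 0.895, 0.871 and 0.914 without PBS replicates 2, 4 and 5 and an adjusted p = 0.884 and 0.805 without HDM replicates 2 and 5. The yolk, eggshell and ovary list had 0.707, and its lead member, the vitelline membrane gene Vm26Aa, had a log2 fold change of 0.43 ± 0.18, or 0.27 without HDM replicate 3. Camera's direction differed from the sign of the list's median or mean in melanization (down, median -0.1, mean 0.01), heat shock (down, median 0.03, mean -0.06), JNK (up, median -0.06, mean -0.01), redox defence (down, median 0.03, mean -0.03) and the ovary list (up, median 0.08, mean -0.16). With 1 library left out the mean ranged from -0.1 to 0.16 for melanization, -0.18 to 0 for heat shock, -0.08 to 0.09 for JNK, -0.06 to 0 for redox defence and -0.3 to -0.03 for the ovary list.

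The yolk protein gene Yp1 was abundant in all 10 libraries, at 9920 ± 3510 CPM in PBS and 7830 ± 1810 CPM in HDM libraries (SD, n = 5). The log2 fold change of Yp1 was -0.34 ± 0.25, or -0.14 without PBS replicate 1. In the accessory gland list Acp26Aa lay between 0 and 0.264 CPM, and 2 members were measurable enough to test, led by Obp56g at a log2 fold change of -0.76 ± 0.32. In the testis list 4 genes were testable, led by bgcn at 0.34 ± 0.27, or 0.16 without HDM replicate 1. Members of this list had unlike levels, with bam at 13.2 to 28.6 CPM and gdl at 17.7 to 30.6 CPM but betaTub85D between 0 and 0.282 CPM. Both bam and gdl were chosen for naming after their values were seen. The difference in mean log2 CPM was -0.42 for the accessory gland list (exact permutation p = 0.103, two-sided) and 0.12 for the testis list (exact permutation p = 0.302, two-sided), the latter 0.04 without HDM replicate 1 and 0.19 without HDM replicate 5. With the looser filter camera gave an adjusted p of 0.92 for 15 accessory gland genes and 0.193 for 14 testis genes. In these 2 lists 0 members passed adjusted over the list alone.

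The largest difference between libraries did not follow the injection. Component 1 of a principal component analysis of log2 CPM held 43.5% of the variance, with mean scores of -5 in PBS and 5 in HDM libraries (exact permutation p = 0.611, two-sided). Its low end held PBS replicates 1 and 3 and HDM replicates 5 and 2, at -42.5, -28.8, -28.6 and -23.8, and its high end HDM replicate 1 at 42.9, PBS replicate 4 at 28.3 and HDM replicate 4 at 26.3. The digestive enzyme score was 0.89, 1.57, 1.24 and 0.54 above the mean of the 10 libraries in those 4 low-end libraries, and -2.14, -1.07 and -0.88 in the 3 at the high end. The fat body score was 1.08 in PBS replicate 1 and -0.59 in HDM replicate 1. Component 3, with 10.7% of the variance, had mean scores of 9.7 in PBS and -9.7 in HDM libraries (exact permutation p = 0.0238, two-sided, or 0.0714 adjusted over the 3 components examined).

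**Figure D3:**
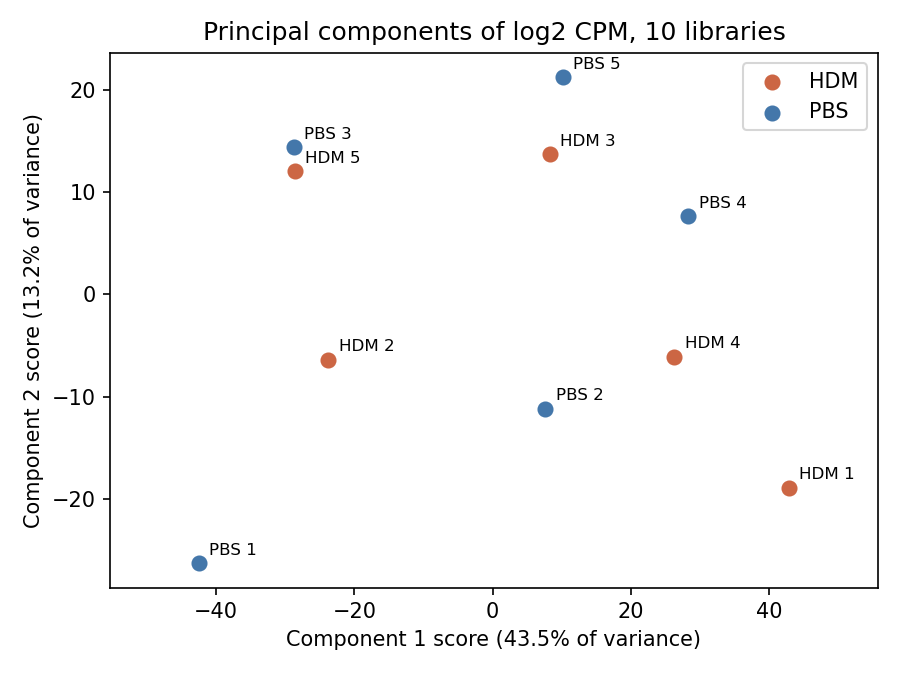
Scores of the 10 libraries on components 1 and 2 of log2 CPM, coloured by injection. PBS and HDM libraries lie at both ends of component 1, which ranges from -42.5 to 42.9.

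For a gene of median precision the SE of the log2 fold change was 0.1. In counts simulated for this comparison over 9950 genes with the measured spread, the test recovered 25 of 50 genes changed 1.5-fold, 38 of 50 changed 2-fold, 46 of 50 changed 4-fold and 49 of 50 changed 8-fold, with 4 unchanged genes called. The changed genes were drawn at random from all tested genes and varied independently. These counts therefore do not carry over to the more variable immune effector genes. The SE was 0.71 for Dro and 1.2 for SPH93, whose log2 fold change of 3.02 had an adjusted p of 0.94 by edgeR.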

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

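Of the weighed tests, those of PBS replicate 1 against the other PBS libraries, of PBS replicate 1 against HDM replicate 2, of HDM replicates 1, 3 and 4 against the PBS libraries, and with component 1 as a covariate were chosen after the values were seen. The library splits and the length check were set up before their results.

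A sample far from the others of its group was looked for among 212 groups of 5 values, covering 35 list scores, 68 named genes, the library totals and 2 components. Chance alone passes the limit in about 1 in 20 groups, and 4 passed. The insulin and FOXO score of HDM replicate 4 was the lowest of the HDM libraries, with a gap to the next that was 0.742 of the range. The log2 CPM of Ire1, an endoplasmic reticulum stress sensor, was highest in HDM replicate 1 (76.8 CPM), with a gap of 0.73 of the range. Vm26Aa, a vitelline membrane gene, was highest in HDM replicate 3 (2960 CPM), with a gap of 0.718 of the range. TotX, a Turandot gene, was highest in the same library (4.81 CPM), with a gap of 0.721 of the range. By this measure 0 values passed in PBS replicate 1, HDM replicate 2 or HDM replicate 5. A gap to the next value cannot flag HDM replicates 2 and 5 where both are high, as in Vago (32.2 and 52 CPM). The lack of a flag there is therefore no sign that they resemble the other HDM libraries.

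The first pattern weighed is that 8 lists moved at the preset correlation. Chance cannot be excluded, since 76 of 100 splits of the libraries gave at least 8 lists, with up to 23 in another split. The middle 95% of 10000 random lists matched on gene length had median log2 fold changes from -0.04 to 0.04, while the 58 oxidative phosphorylation genes had -0.24, which argues against length as the cause for the oxidative phosphorylation genes. With component 1 as a covariate, the oxidative phosphorylation score difference went from -0.22 to -0.17 ± 0.13 (SE). Without PBS replicate 1 it was -0.13 and without PBS replicate 4 -0.34. Component 1 was not shown to measure body tissue against ovary. The ovary list score had a correlation of -0.44 with it, of the same sign as the fat body score at -0.89. An unequal share of body tissue and ovary thus cannot be told apart from an effect of the injection with this covariate and at this spread. An effect of the extract stays open and untested beyond these values.

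The second pattern is the high level of photoreceptor genes in PBS replicate 1. It exceeded the mean of the other 4 PBS libraries by 1.45 in the photoreceptor score, 1.04 in the neuron score and 0.68 in the muscle score. The photoreceptor excess was 0.77 above the muscle excess, where the same difference had an SD of 0.7 in the other 4 libraries, so more body tissue in general cannot be told apart from other causes at this spread. The neuron excess was 0.36 above the muscle excess (SD 0.4), so a larger share of head tissue cannot be told apart either. The design gives no group for a difference within the PBS libraries, so no biological explanation was tested.

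The third pattern is that Drs, Dro, SPH93, Vago, Nazo and LysX were highest in HDM replicates 2 and 5. LysX, a lysozyme gene, had 19 and 8.93 CPM there and at most 0.482 CPM in the other 8 libraries, and Nazo had 5.39 and 7.24 CPM against at most 1.44. Over all 45 measured members of the antimicrobial peptide, Bomanin and RNA interference lists, the median log2 ratio of PBS replicate 1 to HDM replicate 2 was -0.18, with list medians of -0.63, 0 and -0.31, so a share of body tissue cannot be told apart from other causes, as the lists differ. HDM replicates 1, 3 and 4 exceeded the highest PBS library in 17 of 147 gene and library pairs over these lists and the Turandot genes. These were 4 of 39 pairs among the antimicrobial peptides and 1 of 60 among the Bomanins. In the RNA interference list there were 6 of 36, and among the Turandot genes 6 of 12. The share of such pairs without any response was not computed, and the lists differ, so a response shared by every HDM library stays open. A response in part of the HDM libraries or an infection of the flies may also account for the pattern, and both are untested.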

How the results depend on the processing

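Added after seeing the data were component 1 as a covariate, surrogate variables, the omission of 3 libraries, the permutation of list scores and an estimated correlation combined with another change. The count of 0 genes was the same under the alternatives chosen earlier except DESeq2, with 1 gene, 1 of them higher (His3:CG33845). With 2 surrogate variables there were 2 genes, 2 of them lower (CG9897 and CG8740), and with PBS replicate 1 and HDM replicates 2 and 5 left out 1 gene, 1 of them lower (Unc-115b). Leaving out each library in turn gave 0 to 0 genes, and genes at an unadjusted p under 0.05 went from 112 without PBS replicate 1 to 655 without PBS replicate 4. The replicate numbers gave no sign of pairing. Correlations of same-numbered deviations were -0.35, -0.13, 0.12, 0.35 and -0.1, 2 of 10 libraries correlated best with their own number, a hint from the data and not the design, and the replicate block gave 0 genes, 96 at an unadjusted p under 0.05 and 8 lists.

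Of 8 lists called, 0 were called with an estimated correlation, and 0 when each library was also left out. With component 1 or the looser filter as well 0 were called, and 0 by fry and by permutation of list scores. An estimated correlation rarely called a list over the library splits. Permutation could call lists only if several came near its smallest possible p, 0.00794. At the preset correlation the number called lay between 7 and 12 with each library left out. With the 3 libraries left out it was 7, of which 4 were among the 8. Muscle (adjusted p = 0.256) and glycolysis (0.0653) were lost, hemocyte markers, cytochrome P450 and Malpighian tubule genes gained, and the adjusted p, in the other direction, was 0.589 for RNA interference and STING and 0.363 for ribosomal proteins. An estimated correlation was not run with these 3 libraries left out, so the gains hold for the preset correlation only. The looser filter gave 10 lists (the Turandot genes and lysozymes besides the 8), ranks gave 10 (cytochrome P450 and fat body besides the 8) and component 1 gave 12, of which 7 were among the 8, with digestive enzymes lost (adjusted p = 0.264). Of 1823 log2 fold changes of 68 named genes, 1796 kept their direction. Those that turned were Dro (-0.03), Vago (-0.22), Drs (-0.25), Nazo (-0.8), CG42825 (-1.42) and Mtk (-1.45) without the 3 libraries. Each of these had its highest HDM values in HDM replicates 2 and 5, so leaving those out lowered it by design. With quality weights the genes that turned were Lsp2 (0.51) and Mtk (-0.82). With the block they were Mtk (-0.02) and BomS1 (0.18), and with 2 surrogate variables Mtk (-0.04) and BomS1 (0.09). BomS1 also turned with voom (0.21), the Wilcoxon values (0.21), both TPM offsets (0.34 and 0.34), component 1 (0.17) and 1 surrogate variable (0.15). With each library left out, BomS1 ranged from -0.65 to 0.26, Mtk from -0.64 to 0.51, TotX from -0.38 to 0.78 and gdl from -0.01 to 0.19. The cause of the other turns was not tested. A filter on low normalized values was not run, as the table holds counts.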

Other observations

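The hypothesis here, that the real grouping is no stronger than other groupings, was tested with library splits set up before their results.

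Besides Vago and Nazo, CG42825, a STING-regulated gene, had 28.2 and 31.5 CPM in HDM replicates 2 and 5 and at most 3.78 CPM in the other 8 libraries. PGRP-SC1a, an amidase that degrades peptidoglycan, had 31.2 and 42 CPM in those libraries, 11.3 CPM in HDM replicate 4 and 9.94 CPM in PBS replicate 1. TotA and TotC were highest in another library, HDM replicate 3, at 75.4 and 75.3 CPM. Unc-115b had 29.7, 27 and 24.8 CPM in HDM replicates 1, 3 and 4, 45.3 and 82.2 CPM in HDM replicates 2 and 5 and 52 to 65.5 CPM in PBS libraries.

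Since no count is below 0, all 100 of 100 splits had to reach the real count of 0 genes, which says nothing about chance. Of the other splits 6 called any gene, up to 3424. Chance cannot be excluded for the 214 genes at an unadjusted p under 0.05, as 46 of 100 splits gave as many, up to 5045. The split with 3424 genes set PBS replicates 1, 2 and 3 and HDM replicates 2 and 5 against the others, and the next, with 2075, set PBS replicates 1 and 3 and HDM replicates 2, 3 and 5 against the others. Counts this far above the real one point to a structure of the samples apart from the injection. Both splits put the 4 libraries at the low end of component 1 on one side, which follows from how component 1 is defined and is not separate evidence.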
